A study of Homo sapiens with 10 samples.

How the data were processed

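RNA sequencing of the V16A prostate cancer cell line was analysed in 2 experiments with separate controls. The first had 2 control siRNA libraries and 2 libraries with an siRNA against the long isoform of PCAT19. The second had 2 control libraries and 2 libraries with each of 2 siRNAs against HNRNPAB. Libraries were made with a strand-specific mRNA kit and sequenced as single 50 bp reads, per the labels' protocols. TopHat2 version 2.1.0 and the genome build hg19 are named in the submitters' processing notes. The counting tool, its annotation and its strand setting are not given in the sources used here. The authors deposited the values as raw counts per gene symbol, whole numbers with no normalization, in 1 table per experiment with 27044 symbols each. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

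Columns were matched to samples by name. The HNRNPAB table numbers its siRNAs 1 and 2 while the sample titles use another numbering, and nothing links the 2 numberings, so siRNA 1 and siRNA 2 here follow the table. All value columns of both tables were used. Total counts were 17017878 to 26322934 per library in the PCAT19-long table and 562214 to 605442 in the HNRNPAB table.

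Counts were fitted per table with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM scaling and the quasi-likelihood F test, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The 3 groups of the HNRNPAB table shared 1 fit. Standard errors (SE) of log2 fold changes were derived from the F statistic. A change was called shared by the HNRNPAB siRNAs when it passed with each in the same direction. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, for lists with at least 5 tested members. The 32 lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined.

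The naming rule took HNRNPAB and PCAT19. It took, per main comparison, up to 8 genes per direction with the largest change among those that passed, with a mean of at least 5 CPM and every knockdown library beyond every control library. It also took up to 4 passing members per list, a set of genes named in advance (among them MKI67, CCNB1, CDK1, CDKN1A, MYC, E2F1, KLK3, TGFB1 and CEACAM21), up to 5 genes per direction shared by both experiments and the 4 features per direction with the largest difference between the HNRNPAB siRNAs. No gene passed in the PCAT19-long comparison. The genes named there were therefore chosen after their values were seen, as DESeq2 calls or as list members with the smallest unadjusted p, with both knockdown libraries on the same side of both controls. Some genes that the rule names are not reported here.

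The HNRNPAB table was examined for strand after its values were seen. Among 89 abundant genes with no gene on the opposite strand, with a mean of at least 20000 counts in the PCAT19-long controls, the median count in the HNRNPAB controls was 0.130% of that. Symbols whose exons overlap exons on the opposite strand held 61.2% of the HNRNPAB-table control counts and 17.5% of those in the PCAT19-long table. Across 1748 overlapped symbols, the HNRNPAB-table control count had a Spearman rho of 0.466 with the count predicted from the opposite-strand gene and of -0.106 with the symbol's own level. Genes are not independent replicates in these correlations. Each row of this table is therefore called a feature, its value is described as opposite-strand reads, and this reading is inferred, not stated by a label. At least 200 HNRNPAB-table control counts were held by 391 symbols with an overlap and by 94 with none. Annotated overlaps do not account for those 94. Overlaps and names came from GENCODE 29 on GRCh38, which is another build than hg19, so no coordinates are given; 89.1% of symbols were found in it.

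A feature was read as the overlapping gene when the exon overlap was at least 50 bp, at least 80% of the predicted counts came from 1 gene, the prediction reached 25% of the observed count, and carry-over from the feature's own gene was under 20%. The prediction scaled the overlapping gene's count in the PCAT19-long controls by the overlap length. It assumed that the PCAT19-long table was counted without regard to strand, with reads in overlaps left out. Read density was therefore taken from exons free of overlap where at least 200 bp of them remained. Under that assumption, PCAT19-long counts can also hold opposite-strand reads from outside annotated overlaps. These rules gave 1476 features, of which the best-covered 1 per gene among those tested gave 1129 genes. All of these thresholds were chosen after seeing the data, and the prediction minimum had also been set to 10% during the work after an earlier density estimate left out TYMS. Results with 10%, and with 95% of the prediction from 1 gene, are in the closing section. Of 42 genes read through more than 1 feature, 12 had both features past the threshold for the mean siRNA effect, and 9 of these 12 moved in 1 direction. Over all 42, the mean log2 fold changes of the 2 features correlated at 0.452. The prediction had no upper limit, so a feature with far fewer reads than predicted could also be read as the overlapping gene.

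The alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, only the 2 groups compared, camera with an estimated correlation and fry. For lists, the DESeq2 setting used cameraPR on its Wald statistics, added after seeing the data. When a library was left out, the lone library of its group was assumed to vary like the others. The gene-by-gene fits with edgeR, DESeq2 and limma-voom were tested on simulated data with 200 changed genes. In the simulated PCAT19-long comparison of 14128 genes, edgeR recovered 9% of genes changed by 1 log2 unit and 83% of those changed by 2, with 9 false calls among 101. DESeq2 recovered 26% and 93%, with 48 false calls among 167. In the simulated HNRNPAB comparison of 5870 features, edgeR recovered 89% and 99% for siRNA 1 with 10 false calls, and 80% and 99% for siRNA 2 with 2. For lists, 1 simulated data set held 20 lists of 40 genes, 1 of them changed. Camera with the preset correlation called the changed list and no other, while the estimated correlation gave the changed list an adjusted p of 0.107. The simulated genes varied independently, so this cannot show whether the preset correlation gives false calls for lists whose members vary together.

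The comparisons by side across both experiments, a family of 5 Fisher's exact tests with Benjamini-Hochberg adjustment, were chosen after seeing the data. Replicates were compared by a chi-square statistic of their counts divided by its degrees of freedom. It was 3.06 for the PCAT19-long controls and 110.2 for its knockdown libraries. In the HNRNPAB table it was 1.10, 1.08 and 1.17 for controls, siRNA 1 and siRNA 2, just above the value of 1 that sampling noise gives. All libraries were kept as separate replicates.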

Results

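V16A prostate cancer cells were profiled by RNA sequencing in 2 knockdown experiments. In the first, an siRNA against the long isoform of PCAT19, a long non-coding RNA gene, was compared with a control siRNA, with 2 libraries per group. In the second, 2 siRNAs against HNRNPAB, which encodes an RNA-binding protein of the hnRNP family, were each compared with the same 2 libraries of a control siRNA, again with 2 libraries per siRNA. Total counts were 24660403 and 26322934 in the controls and 22008684 and 17017878 in the knockdown libraries of the PCAT19-long table. They were 601399 and 605442 in the controls, 576408 and 590546 with siRNA 1, and 564262 and 562214 with siRNA 2 of the HNRNPAB table.

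The targeted genes gave no check of the labels. PCAT19 was not analysed here. In the PCAT19-long table HNRNPAB had 4408 and 4499 counts in the controls and 4392 and 2088 in the knockdown libraries, a log2 fold change of -0.13 (SE 0.28, edgeR adjusted p = 0.916). This was -0.53 without knockdown replicate 1 and 0.19 without replicate 2. The counts of the HNRNPAB table are read here as opposite-strand reads, so its HNRNPAB feature checks nothing. It had 161 and 205 counts in the controls, 139 and 149 with siRNA 1 and 156 and 158 with siRNA 2.

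The PCAT19-long comparison asked which genes respond to loss of the long isoform. Genes of DNA replication, cell division and recombination repair were lower as groups by camera with the preset correlation, and listed replication-dependent histone genes were higher. With an estimated correlation none of the 4 groups passed, at adjusted p = 0.575 for replication, 0.827 for mitosis, 0.683 for recombination and 0.683 for histones. The median log2 fold change was -0.73 over 53 genes of DNA replication and the G1/S transition, and 47 of them lay below both controls in both knockdown libraries. It was -0.82 over 67 mitotic genes, of which 64 did so, and -0.64 over 32 genes of homologous recombination and the Fanconi anaemia pathway, of which 22 did so. Histone genes, whose near-identical copies make the counts of single members uncertain, had a median of 0.77 over 20 genes, and 11 lay above both controls in both libraries. Chance places 16.7% of genes on a given side when 2 libraries are compared with 2 that spread alike. The knockdown libraries spread more than the controls, so the background is higher. Of all 14128 genes tested, 3204 lay below and 3086 above both controls in both knockdown libraries.

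With the preset correlation, camera's adjusted p was 1.61e-20 for replication, 1.87e-20 for mitosis, 8.06e-10 for recombination and 2.09e-05 for histones. Over all genes tested by edgeR, no member of these lists passed. Adjusted over the list alone, 23 replication genes, 12 mitotic genes and 13 recombination genes passed as lower, and 4 histone genes as higher. Cytosolic ribosomal protein genes, which also have near-identical copies, had a median of -0.29 over 68 genes, 60 of them below both controls in both libraries (adjusted p = 5.69e-11, and 0.575 with an estimated correlation). Listed long non-coding RNAs had a median of -0.40 over 18 genes (adjusted p = 0.00122, 0.575 with an estimated correlation, and 0.0911 without knockdown replicate 1). Listed p53 targets had a median of -0.26 over 29 genes (adjusted p = 0.0416, and 0.827 with an estimated correlation). The p53 result was also lost without control 1 (0.103), control 2 (0.0622) or knockdown replicate 2 (0.672), with DESeq2 (0.0780) and with no filter (0.130). The other 21 of the 28 lists tested did not pass.

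**Figure D1:**
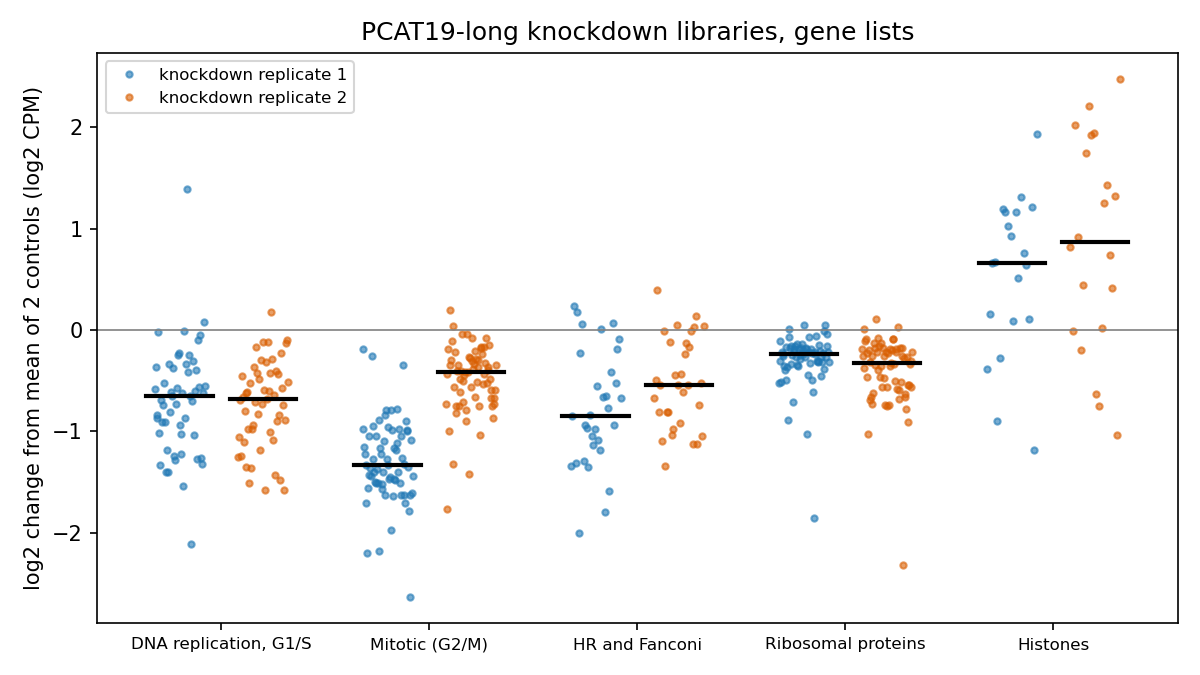
Each point is 1 gene's log2 change in 1 PCAT19-long knockdown library from the mean of the 2 controls, on the log2 CPM scale, for 5 gene lists, and black bars are list medians. The mitotic median was -1.33 in knockdown replicate 1 and -0.42 in replicate 2, and the replication medians were -0.66 and -0.68.

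No single gene passed edgeR's test among 14128, while 1388 had an unadjusted p under 0.05 against 706 by chance. DESeq2 called 13 genes higher and 88 lower, and limma-voom called 0. In a simulation of this design DESeq2 made 48 false calls among 167, so its calls are read with caution. Among DESeq2 calls, chosen after their values were seen, ABCB11, the bile salt export pump, had -3.46 (SE 0.28). CDCA7L had -2.12 (SE 0.14), TNFRSF19 -2.04 (SE 0.19) and PHLDA1 -2.01 (SE 0.15). Of the replication genes, CDC45, a part of the replicative helicase, had -1.46 (SE 0.15) and CDT1, a licensing factor, -1.39 (SE 0.16). AURKB, a mitotic kinase, had -1.38 (SE 0.16), and CHEK1, a checkpoint kinase, -1.03 (SE 0.15). Among DESeq2 calls that were higher, HIST2H2BE had 2.23 (SE 0.25) and NPC1, a cholesterol transporter of the lysosome, 1.43 (SE 0.18). Each of these genes had edgeR adjusted p = 0.447, and each had both knockdown libraries beyond both controls on the same side. Fits with 1 knockdown library left take their spread from the 2 controls, which differed far less, so passing there gives these genes no support. With replicates paired as a replicate block, ABCB11 passed edgeR's test (-3.47, adjusted p = 0.0481).

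Of the genes named in advance, MKI67 had a log2 fold change of -0.83 (SE 0.38), CCNB1 -0.75 (SE 0.28), CDK1 -0.43 (SE 0.22), E2F1 -0.27 (SE 0.15) and KLK3 -0.23 (SE 0.15), all below both controls in both knockdown libraries. CDKN1A had 0.24 (SE 0.16). MYC had -0.38 (SE 0.49), -1.27 without knockdown replicate 1 and 0.16 without replicate 2. Without knockdown replicate 1 and without replicate 2, MKI67 had -0.39 and -1.46, CCNB1 -0.44 and -1.15, CDK1 -0.73 and -0.19, and E2F1 -0.29 and -0.25. KLK3 had -0.10 and -0.38 and CDKN1A 0.08 and 0.39. None of these passed with all libraries, with edgeR adjusted p from 0.504 for CCNB1 to 0.838 for MYC. TGFB1 had at most 3 counts per library and CEACAM21 at most 1.

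The SD of the log2 ratio between the 2 knockdown libraries was 0.712, against 0.135 between the controls, over 11890 genes. Without knockdown replicate 1 edgeR called 3849 genes higher and 4024 lower, and without replicate 2 it called 4061 and 3989; without either control it called 0. Over all genes tested, 3086 lay above and 3204 below both controls in both knockdown libraries, 44.5% together. Chance gives 33.3% only when all libraries spread alike. The knockdown libraries spread more than the controls, so the share expected without a shared response is higher and was not estimated. The 44.5% is therefore not read as a shared response.

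The HNRNPAB comparison asked which genes respond to knockdown with 2 separate siRNAs. Read as the gene overlapping on the opposite strand, an inferred reading chosen after seeing the data, mitotic genes and recombination genes were lower with both siRNAs. Camera with the preset correlation gave the mitotic genes adjusted p = 1.02e-06 and 0.000252, and the recombination genes 0.000152 and 0.00313, with siRNA 1 and siRNA 2. With an estimated correlation the adjusted p was 0.298 for both lists with siRNA 1 and 0.413 for both with siRNA 2, so neither passed. Of 9 mitotic genes that could be read this way, 9 were lower with siRNA 1 and 8 with siRNA 2, with median log2 fold changes of -2.29 and -1.37. HMMR, a spindle protein, had -2.23 (SE 0.13) with siRNA 1 and -3.27 (SE 0.15) with siRNA 2. NCAPG, a condensin subunit, had -2.48 (SE 0.12) and -2.08 (SE 0.12), PRC1, which bundles spindle microtubules, -2.13 (SE 0.11) and -1.95 (SE 0.11), and SGO1, which protects cohesin, -2.61 (SE 0.16) and -1.80 (SE 0.14).

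Of 5 recombination and Fanconi genes, 5 were lower with siRNA 1 and 4 with siRNA 2, with medians of -1.93 and -1.21. EME1, a subunit of a structure-specific nuclease, had -2.07 (SE 0.20) and -1.78 (SE 0.19), and FANCI -2.08 (SE 0.11) and -1.31 (SE 0.10). The member short of the threshold with siRNA 2 was FANCL, at -0.27, and among mitotic genes CDC25C, at -0.65. Adjusted over the list alone, all 9 mitotic and all 5 recombination genes passed with each siRNA. Replication genes were too few for a list test. TYMS and CCNE2 were lower with both siRNAs, while MCM7 passed with neither, at 0.41 (SE 0.18) and -0.11 (SE 0.20). CCNE2 did not pass with DESeq2 (adjusted p = 0.0963 and 0.0684). The other lists with 5 or more readable genes, ribosomal proteins, splicing factors and apoptosis regulators, did not pass camera with either siRNA. With fry, which does not compare a list with other genes, splicing factors passed as lower with both siRNAs (adjusted p = 0.00166 and 0.00165, medians 0.03 and -0.33, so the median and the test differ in sign with siRNA 1). Apoptosis regulators passed fry as higher with siRNA 1 (0.0154) and ribosomal proteins with siRNA 2 (0.0101). Of the 5 splicing genes, 2 were lower and 1 higher with siRNA 1, and 3 lower and 1 higher with siRNA 2. SNRPD3, a core splicing protein, had -2.25 (SE 0.16) and -2.13 (SE 0.16), while EFTUD2 was higher with siRNA 2 at 2.39 (SE 0.34) and SF3A1 with siRNA 1 at 0.65 (SE 0.09), the last 2 genes chosen after their values were seen.

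**Figure D2:**
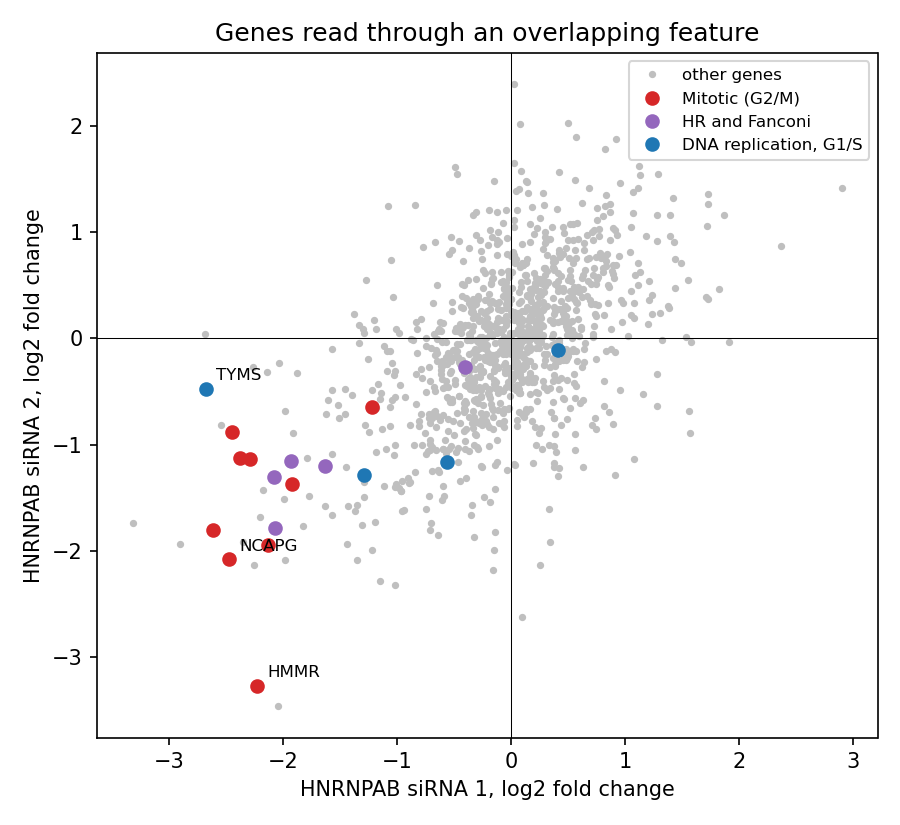
Each point is 1 of 1117 genes read through an overlapping feature and tested in both experiments, with its log2 fold change with HNRNPAB siRNA 1 on the x axis and siRNA 2 on the y axis. The mitotic genes lie in the lower left, and TYMS lies at -2.68 and -0.47.

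**Figure D3:**
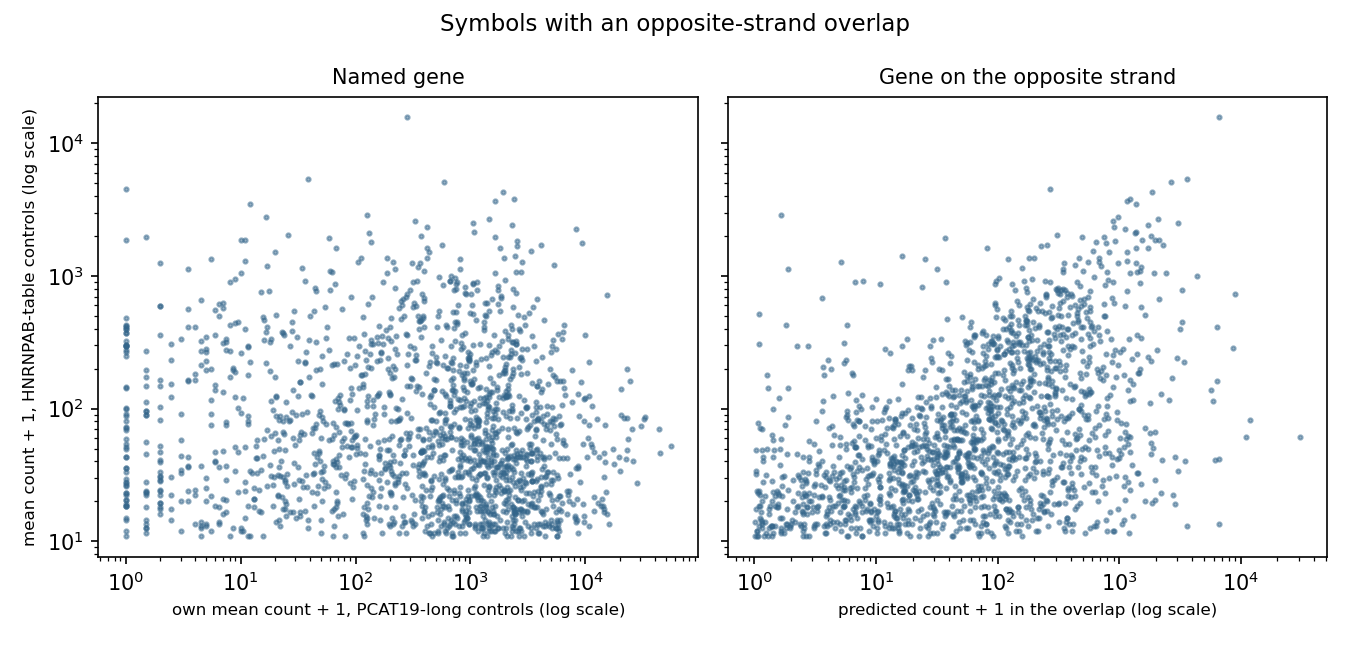
Each point is 1 of 1748 symbols with an opposite-strand overlap, and both axes are on log scales. The HNRNPAB-table control count had a Spearman rho of -0.106 with the named gene's own count (left) and 0.466 with the count predicted from the opposite-strand gene (right).

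Over all 5870 features tested by edgeR, siRNA 1 gave 727 higher and 734 lower, and siRNA 2 gave 983 higher and 1020 lower. DESeq2 gave 322 and 349 for siRNA 1, and 486 and 552 for siRNA 2. With at least a 2-fold change the edgeR counts were 269 and 358 for siRNA 1, and 444 and 560 for siRNA 2. Both siRNAs shared 304 higher and 439 lower features (DESeq2 132 and 199), against 122 and 128 for independent lists of these sizes, and 124 features passed in opposite directions. The correlation of the 2 siRNA effects across features was 0.520, against 0.494 for unchanged groups simulated against the same controls (40 draws), and their covariance was 0.313 against 0.0506. These groups shared 0 calls, but they also gave a mean of only 0 and 0.025 calls, so they do not show how many shared calls the common controls add to real effects. Read as opposite-strand genes, 98 were higher and 137 lower with both siRNAs among 1129 (DESeq2 51 and 74).

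Leaving out 1 library lowered some of these counts. The siRNA 1 counts fell to 414 higher without its replicate 1, and to 411 higher and 431 lower without its replicate 2. The shared higher features were 190 without control 1, 182 without siRNA 1 replicate 1 and 174 without its replicate 2, and the shared lower features 281 without siRNA 1 replicate 2. The opposite-strand genes higher with both siRNAs were 63, 62 and 62 without control 1, siRNA 1 replicate 1 and its replicate 2.

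Features with the largest shared changes mostly had no assigned gene. The opposite-strand reads at AGAP2-AS1 had a log2 fold change of 3.11 (SE 0.21) with siRNA 1 and 2.98 (SE 0.22) with siRNA 2, and those at LOC105377267 of 2.86 (SE 0.19) and 3.07 (SE 0.18). GAPDH had 6 and 1 counts in the controls, 84 and 72 with siRNA 1 and 101 and 82 with siRNA 2. PCDHA11, whose exons are shared along its cluster, had 0 and 0 counts in the controls, 27 and 20 with siRNA 1 and 9 and 19 with siRNA 2. AMN, SLC2A6, TFAP2E and KRTAP5-2 completed the higher group; TFAP2E did not pass with siRNA 1 with no filter on low counts (adjusted p = 0.0519). GLP1R had -2.96 (SE 0.14) and -2.60 (SE 0.14), and TM4SF18 had 16 and 18 counts in the controls and 0 in each knockdown library. HIST1H2AL, a histone gene with near-identical copies, FLG, C8orf58, WHAMMP2, LOC101929705 and NVL completed the lower group; NVL did not pass with siRNA 2 without control 2 (adjusted p = 0.0874). KLK3, a kallikrein gene of the prostate with no overlapping gene, had 17 and 24 counts in the controls, 5 and 3 with siRNA 1 and 2 and 3 with siRNA 2 (edgeR adjusted p = 0.000157 and 1.12e-05); with siRNA 1 it did not pass without control 2 (adjusted p = 0.0572). DESeq2 gave no adjusted p for KLK3, NVL or TM4SF18. In the controls KLK3 was at 0.0322% of its PCAT19-long control count, against a median of 0.130% for the 89 abundant genes. It ranked 1 from the lowest of these with siRNA 1 (0.00629%) and siRNA 2 (0.00393%). Carry-over from the named strand could give all KLK3 counts, so whether opposite-strand reads changed there cannot be told. Tested by the features' own names, 1 of 20 lists passed camera with siRNA 1, mitotic genes as lower (adjusted p = 0.00997, and 0.654 with an estimated correlation). With siRNA 2, 0 passed (smallest camera adjusted p = 0.0854). The siRNA 1 call was lost with DESeq2 and with fry (adjusted p = 0.0802). With siRNA 2, lists passed with no filter and with fry, among them mitotic genes as lower (fry adjusted p = 0.0171).

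The 2 HNRNPAB siRNAs differed at 893 features in each direction, 1786 in all by edgeR, and at 1151 without siRNA 1 replicate 2. DESeq2 gave 885 and edgeR with no filter on low counts 993. Replicates of this table differed little more than sampling noise gives, and no label says they are separate cultures. If they are not, differences between single cultures would pass too, here and against the controls. TYMS, the thymidylate synthase gene read through ENOSF1, had -2.68 (SE 0.07) with siRNA 1 and -0.47 (SE 0.06) with siRNA 2 (edgeR adjusted p of the difference 3.46e-57). By feature name, the opposite-strand reads at COL16A1, EIF1AX, MYOM1 and SLC37A1 were higher with siRNA 1 than with siRNA 2, at low counts. COL16A1 had 23 and 17 counts with siRNA 1 and 2 and 0 with siRNA 2, EIF1AX 10 and 8 against 0 and 1, MYOM1 10 and 7 against 0 and 1, and SLC37A1 14 and 16 against 2 and 0. IQCD, COL5A1 and LOC105371184 were lower with siRNA 1 than with siRNA 2. IQCD had 1 and 4 counts against 27 and 47, COL5A1 3 and 2 against 33 and 35, and LOC105371184 1 and 1 against 20 and 11. CDKN1A opposite-strand counts were 29 and 24 in the controls, 16 and 14 with siRNA 1 and 62 and 73 with siRNA 2 (edgeR adjusted p = 0.0640 and 8.03e-08). Part of these CDKN1A counts can be carry-over from the named strand. The features MKI67 and MYC did not pass with either siRNA in the fit of all 3 groups; MKI67 passed as lower with siRNA 2 with RLE (-1.05, adjusted p = 0.0480) and with only the 2 groups compared (-1.06, adjusted p = 0.0444).

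The last comparison asked whether the knockdowns of PCAT19-long and HNRNPAB change the same genes. Of 18 replication, mitotic or recombination genes measured in both experiments, 15 were lower with both HNRNPAB siRNAs, and 14 of these 15 lay below the controls in both PCAT19-long knockdown libraries. Most members of these lists did so after PCAT19-long knockdown, so this count is no separate test of a shared response. CCNA2, a cyclin of S phase and mitosis, had a log2 fold change of -1.32 after PCAT19-long knockdown, and -2.29 and -1.13 with the HNRNPAB siRNAs. PKMYT1, a kinase that acts on CDK1, had -1.47, -2.18 and -1.43. These are 2 of 6 genes that DESeq2 called lower in both experiments, chosen after their values were seen; the others were CDCA7L, EME1, MDC1 and TYMS.

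With edgeR 0 genes were called in both experiments, since it called 0 of the PCAT19-long changes, with 1388 genes at an unadjusted p under 0.05. Limma-voom also gave 0, and DESeq2 gave 6 lower and 0 higher. Fits with 1 PCAT19-long knockdown library left gave genes called in both. Those fits took their spread from the 2 controls and called a large share of all genes, so the overlap is not read as shared changes.

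Over all 1117 genes measured in both, 36.5% of the 137 lower with both HNRNPAB siRNAs lay below the controls in both PCAT19-long libraries, against 18.9% of the other 980 (2-sided Fisher's exact test across genes, p = 9.29e-06, adjusted over 5 such tests 4.64e-05). Leaving out the listed cell cycle and repair genes, the shares were 29.5% and 18.7% (exact p = 0.00779, adjusted 0.0130). Cell cycle genes on none of these lists, such as PKMYT1, stayed in, so these shares do not show a response outside the cell cycle. For genes higher the shares were 23.7% and 22.5% (exact p = 0.799, adjusted 0.999). Among genes DESeq2 called after PCAT19-long knockdown, 6 of 9 lower genes were also lower with both HNRNPAB siRNAs (exact p = 0.000189, adjusted 0.000471), and 0 of 1 higher genes were also higher (exact p = 1, adjusted 1). These 5 tests were chosen after seeing the data, and genes are not independent replicates. The correlation across genes between the PCAT19-long change and the mean HNRNPAB change was 0.162 by Pearson's r and 0.0882 by Spearman's rho. Pearson's r was 0.172 with knockdown replicate 1 alone, 0.0711 with replicate 2 alone and 0.0783 without the listed genes.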

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

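The 2 siRNAs against HNRNPAB were compared by edgeR's test of the difference between their effects, a test fixed before the data were examined, while the tests read by opposite-strand gene were chosen after the result was seen. The change differed between siRNA 1 and siRNA 2 at 1786 of 5870 features, and at 1151 without siRNA 1 replicate 2, at 885 with DESeq2 and at 993 with no filter on low counts. Among features read as an opposite-strand gene, 500 of 1129 genes differed. Replicates differed little more than sampling noise gives, and no label says they are separate cultures. These tests therefore cannot tell a difference between the siRNAs from 1 between single cultures.

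Several list members named by the rule on gene lists differed between the siRNAs. The difference of siRNA 1 minus siRNA 2 on the log2 scale was -2.20 (SE 0.07) for TYMS, -0.81 (SE 0.20) for SGO1, -0.77 (SE 0.13) for FANCI, -0.75 (SE 0.23) for NOP16, -0.42 (SE 0.17) for FANCA, -0.40 (SE 0.16) for NCAPG and -0.39 (SE 0.15) for RPL38. It was 1.04 (SE 0.21) for HMMR, 0.38 (SE 0.09) for ACAT2 and 0.38 (SE 0.12) for IDI1. TYMS, read through ENOSF1, had 2092 and 2177 counts in the controls, 360 and 294 with siRNA 1 and 1516 and 1378 with siRNA 2. With RPL38, the opposite-strand reads were higher with both siRNAs, and with the other genes given here they were lower with both. RPL38 did not pass with siRNA 1 without siRNA 1 replicate 1 (0.63, adjusted p = 0.0545), and NOP16 did not pass with siRNA 2 with DESeq2 (-0.73, adjusted p = 0.0582).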

How the results depend on the processing

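The alternatives were fixed before the data were examined, except cameraPR on DESeq2 statistics and the opposite-strand reading with its 10% and 95% limits, tests chosen after the result was seen. For each value below that moved, the cause was not tested, except that leaving out a library leaves fewer samples.

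In the PCAT19-long comparison DESeq2 called 13 genes higher and 88 lower against 0 by edgeR, and 6 genes lower in both experiments. With replicates paired as a replicate block, 1 gene, ABCB11, was lower. Leaving out 1 library gave 0 to 4061 genes higher and 0 to 4024 lower, and 0 to 30 higher and 0 to 62 lower in both experiments; all values above 0 came from leaving out a knockdown library. HNRNPAB ranged from -0.53 (without knockdown replicate 1) to 0.19 (without replicate 2) and MYC from -1.27 to 0.16. Lists higher were 2 with RLE and with limma-voom (histones and oxidative phosphorylation), 0 with an estimated correlation and with fry, and 1 to 4 with 1 library left out. Lists lower were 0 with an estimated correlation and with fry.

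In the HNRNPAB comparison DESeq2 and no filter gave 322 and 360 features higher and 349 and 386 lower with siRNA 1, and 486 and 601 higher and 552 and 637 lower with siRNA 2. Shared features were 132 and 130 higher and 199 and 230 lower, opposite-strand genes 51 and 52 higher and 74 and 79 lower, and features that differed between the siRNAs 885 and 993. With 1 library left out, siRNA 1 gave 411 to 716 higher and 431 to 797 lower, both siRNAs shared 174 to 254 higher and 281 to 421 lower features, 62 to 81 opposite-strand genes were higher, and 1151 to 1763 features differed. Opposite-strand genes shared by both siRNAs were 112 higher and 162 lower with the 10% limit, and 93 and 133 with the 95% limit, against 98 and 137. The HNRNPAB feature with siRNA 1 passed at -0.33 with RLE and ranged from -0.50 (without control 1) to -0.16, and with siRNA 2 from -0.32 to 0.013 (without control 2).

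Lists read through an overlapping feature were 0 lower with an estimated correlation for each siRNA, and with fry 1 was higher and 3 were lower for each, against 0 and 2. Lists by the features' own names were, for siRNA 1, 0 lower with DESeq2, an estimated correlation and fry, and 2 lower with no filter. For siRNA 2 they were 2 higher and 5 lower with fry, 2 higher and 5 lower with no filter, and 0 to 2 higher and 1 to 2 lower with 1 library left out.

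Of the values for named HNRNPAB features under the alternatives, 1439 kept their direction and side of the threshold, 82 lost the call, 7 gained it and 1 changed sign. For named PCAT19-long genes 320 kept both, 119 gained the call and 2 changed sign. The 82 include features to which DESeq2 gave no adjusted p, such as TM4SF18 and KLK3, which were therefore not shown to fail. Gains in fits with 1 knockdown library left rest on the spread of the 2 controls alone. Replicate numbers did not act as paired: the difference between replicates correlated across genes at 0.0923 between control and knockdown in the PCAT19-long table, and in the HNRNPAB table at 0.00168 between control and siRNA 1, 0.00450 between control and siRNA 2 and -0.00911 between the siRNAs. Enough counts to test were present for 5870 features of the HNRNPAB table, against 14128 genes in the other table; whether sequencing depth or the strand counted limits this was not tested.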

Other observations

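The tests on the strand, on shallow sequencing, on a mislabelled control and on GAPDH were chosen after the result was seen, while those on thinned controls, transcript length, GC content and 1 response at 2 strengths had their bounds set before.

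The genes in this paragraph were chosen after their values were seen. Of the cholesterol synthesis genes read through an overlapping feature, IDI1, FDPS and ACAT2 were lower with both HNRNPAB siRNAs. IDI1 had a log2 fold change of -1.02 (SE 0.10) and -1.40 (SE 0.10), FDPS of -0.75 (SE 0.07) and -0.89 (SE 0.07), and ACAT2 of -0.58 (SE 0.08) and -0.95 (SE 0.08), while CYP51A1 was at -0.80 (SE 0.42) and -0.82 (SE 0.42) and did not pass. Only 4 members of the list could be read, so the list was not tested. Genes read as higher with both siRNAs included GAS6, a ligand of the TAM receptors, at 1.42 (SE 0.23) and 1.32 (SE 0.23), and FZD4, a Wnt receptor, at 1.11 (SE 0.17) and 1.41 (SE 0.16). The difference between the siRNAs was -1.98 (SE 0.08) for ASPH, read through CLVS1, and 2.38 (SE 0.14) for CAST, read through ERAP1.

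Several lists of the PCAT19-long comparison had medians that differed in sign between the knockdown libraries, and those given here did not pass with TMM scaling and all libraries, by camera on log2 CPM. Where a knockdown library was left out, the spread came from the 2 controls alone, so passing there gives these lists no support. Unfolded protein and stress response genes had a median log2 change of -0.66 in knockdown replicate 1 and 0.19 in replicate 2; they passed as higher without replicate 1 (camera adjusted p = 0.0331) and as lower without replicate 2 (1.01e-07) or control 2 (0.0398). MYC and ribosome biogenesis genes had 0.22 and -0.43, and passed as lower without replicate 1 (3.39e-05) and as higher without replicate 2 (0.00732). Oxidative phosphorylation genes had 0.32 and -0.11, and heat shock genes 0.37 and -0.13; without replicate 2 both passed as higher (9.17e-08 and 0.00501). Cholesterol synthesis genes had -0.12 and 0.14, and passed as higher without replicate 1 (0.0220). With all libraries, oxidative phosphorylation genes had adjusted p = 0.0503, and passed as higher with RLE (0.0498) and with limma-voom (0.0273), against 0.827 with an estimated correlation.

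The PCAT19-long knockdown libraries differed from each other more than the controls did. Lower depth was excluded, since controls thinned to the knockdown totals had an SD of log2 ratio of 0.148, and a mislabelled control was excluded, since the closer knockdown library lay at an SD of 0.531 from the controls. Transcript length (Spearman rho -0.0248 across genes) and GC content (0.0814) were excluded as the whole cause. The changes of the knockdown libraries, each against 1 control library, correlated at r = 0.0833 across genes, and at 0.0354 with the controls exchanged (no label ties a knockdown library to a control), which argues against 1 response at 2 strengths. Different siRNAs, days or cultures behind the libraries stay open and were not tested.

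Abundant mRNAs were near 0 in the HNRNPAB table. Shallow sequencing alone was excluded, since 89 abundant genes took 0.0634 times the share of counts they took in the PCAT19-long table. Counting on the strand opposite to the named gene is a candidate explanation, with a Spearman rho of 0.466 across symbols between control counts and the opposite-strand prediction. No biological explanation was tested.

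GAPDH had few reads in the HNRNPAB-table controls. Less carry-over from the named strand for all abundant genes was excluded, since the larger median log2 change of the others was -0.112. Antisense reads induced by both siRNAs cannot be told apart from ordinary carry-over, since GAPDH reached at most 0.0995% of its PCAT19-long control count, inside the range of the other abundant genes. Less GAPDH mRNA in the control libraries is a candidate explanation, since GAPDH ranked 1 from the lowest of 89 genes there, at 0.00381%, and 26 and 39 with the siRNAs. A control siRNA against GAPDH would give this and was not tested; each HNRNPAB contrast would then also contain the effects of that control.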
